A study of Homo sapiens with 40 samples.

How the data were processed

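The series measured RNA in BEAS-2B cells, an immortalised human bronchial epithelial line, after 2 h of treatment. It held 40 libraries in 10 groups of 4. The groups were as follows: vehicle, roflumilast N-oxide (RNO, an inhibitor of the PDE4 phosphodiesterases that break down cAMP) at 1 uM, ONO-AE1-329 (here ONO, an agonist of the prostaglandin E2 receptor EP4) at 0.1 nM, 1 nM and 1 uM, vilanterol (an agonist of the β2-adrenoceptor) at 100 nM, and each of the 4 agonist treatments together with RNO. Groups and replicate numbers were taken from the sample labels. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

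Libraries were directional poly(A) libraries sequenced on a NextSeq 500 across 2 sequencing kits, and the labels do not say which library was sequenced with which kit. The tools named in the submitters' processing notes are bcl2fastq 2.18.0.12, kallisto and sleuth, with the builds GRCh37 and hg19, and the versions of kallisto and sleuth are not given in the sources used here. The authors deposited a table of 15788 genes by 40 libraries that holds a normalised signal: TPM (transcript abundance scaled for length and depth) adjusted between samples. The column totals lay between 956888 and 1091466 and were not equal. TPM had been assumed before the data were examined, and the values are called TPM in the text with this adjustment understood. The median value of a library lay between 8.47 and 9.11 TPM. No read counts were analysed here, so the depth of each library is unknown and no interval from counting error is given. Of the 15788 symbols, 14274 matched the current list of gene names. A further 1088 matched RefSeq symbols or synonyms, 69 entries named more than 1 symbol, 12 were identical to another entry, and 298 were at 0 in at least 1 library. The annotation at hand was of a later build than the authors', so no coordinates are given.

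Values were transformed to log2(value + 1), and the 12591 genes with a mean of at least 1 TPM over all libraries were tested. A linear model with 1 mean per group was fitted over all 40 libraries with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), with moderated variances and an intensity trend. This left 30 residual degrees of freedom. The 22 comparisons were each treatment against vehicle, each agonist with RNO against that agonist alone, the interaction of each agonist with RNO, 4 comparisons between treatments, and the 1 uM ONO + RNO combination against RNO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and counts with at least 2-fold change are given separately. Folds are ratios of group means in TPM, and log2 fold changes are on the log2(value + 1) scale, which understates the change of genes at low levels. Levels are mean ± SD of 4 libraries, and adjusted p-values of single genes are limma's. Comparisons, lists, tests and alternatives were chosen before the data were examined unless stated. On simulated data 200 of 12591 genes were changed (10 draws). The model recovered 89% of genes shifted by 0.5 log2 in a comparison of 2 groups, with 5.09% false calls. In an interaction it recovered 76.7%, with 5.35% false calls. The simulated values were drawn independently, without differences between replicate numbers or an outlying library. The rates may therefore not hold for the real libraries.

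The genes named in the text follow a rule: for each comparison the 10 highest and 10 lowest log2 fold changes among called genes whose groups of 4 libraries did not overlap, any member of the gene lists, and in every comparison PTGER4 (EP4) and PDE4A, PDE4B, PDE4C and PDE4D. Some results that the rule names are not reported here. PDE4C lay under the mean of 1 TPM and was not tested. Groups of 4 and 4 libraries that differ by chance fail to overlap in 2.86% of genes. That rate is for genes not chosen beforehand. Called genes were chosen on the same libraries, so the counts without overlap given below describe the calls and do not test them.

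The 24 gene lists were written from general knowledge and tested against vehicle with limma's camera at its preset correlation of 0.01, over 180 tests adjusted together. They cover cAMP and CREB response, cAMP synthesis, breakdown and receptors, inflammatory cytokines and chemokines, negative regulators of inflammatory signalling, MAPK phosphatases and Sprouty family, immediate early genes, YAP and TEAD targets, TGF-beta and BMP signalling, growth factors and their receptors, circadian clock, glucocorticoid-responsive genes, unfolded protein and ATF4 response, cell cycle, interferon-stimulated genes, cholesterol synthesis, prostanoid pathway, Notch, Wnt and Hedgehog signalling, ribosomal protein genes, mitochondrially encoded genes, and markers of basal and squamous, ciliated and secretory, fibroblast and mesenchymal, leukocyte and endothelial cells. Counts of list members are of genes called over all genes tested, and counts adjusted over the list alone stand beside them. The test was repeated with an estimated correlation, a pseudocount of 0.1, the replicate block described next and 2 other scalings, and where the call of a list was lost its p is given.

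The replicate numbers come from the labels. After group means were removed, libraries with the same number in different groups correlated across genes with a median r of 0.259 (180 pairs, 174 above 0.1), and libraries with different numbers with a median r of -0.0846 (540 pairs). Libraries of a comparison were taken to pair by number where every pair of equal number had r above 0.1. Counts of called genes with replicate number as a block are given beside the main counts for the comparisons whose libraries paired by number. They are given only in the closing section for the 5 comparisons where 1 or more pairs did not (1 nM ONO + RNO against vehicle and against 1 uM ONO, and the interactions of 1 nM ONO, 1 uM ONO and vilanterol).

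A response score was the mean of log2(value + 1) over the genes called with at least 2-fold change between 1 uM ONO + RNO and RNO, 98 higher and 4 lower. The levels of the other 8 groups did not enter that difference, although all 40 libraries set the variances and the filter used. Scores were compared with 2-sided exact permutation tests of 4 against 4 libraries (70 arrangements, smallest possible p 0.0286), adjusted over the 28 score comparisons. Agreement of log2 fold changes between 1 uM ONO and vilanterol was set against 100 simulated draws without change and against 6 splits of the vehicle libraries into separate controls for each agonist. Each library was also left out in turn, and alternatives changed the pseudocount (0.1 or 2), the filter (none, or a mean of at least 5 TPM), the scaling (each library rescaled to equal totals, or median ratios), the variance estimate (robust), the libraries fitted (only the groups compared) and the design (replicate block). Library weights, the replicate block without vehicle replicate 3, and the gene lists with libraries rescaled to equal totals were added after the data had been seen. Neither scaling moved the median log2 fold change of all genes by over 0.1. No library was excluded, and no 2 libraries held identical values.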

Results

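BEAS-2B cells were treated for 2 h with vehicle, with the EP4 agonist ONO at 0.1 nM, 1 nM or 1 uM, with the β2-adrenoceptor agonist vilanterol at 100 nM, with the PDE4 inhibitor RNO at 1 uM, or with RNO together with 1 of the 4 agonist treatments. EP4 and the β2-adrenoceptor both couple to the formation of cAMP, the second messenger that PDE4 enzymes break down. The series asks which genes the EP4 agonist changed in these airway epithelial cells. Over the 40 libraries the first principal component carried 32% of the variance, and 98.6% of the variance along it lay between groups. The second carried 12.5%, and 95% of the variance along it lay between replicate numbers.

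ONO at 1 uM raised 528 and lowered 380 of the 12591 genes tested. The 3 NR4A orphan nuclear receptors, early targets of cAMP signalling, were among the strongest responses. NR4A3 rose from 1.35 ± 0.495 TPM in vehicle to 36.2 ± 3.94 TPM (SD, n = 4), 26.8-fold (adjusted p = 4.4e-18). NR4A2 rose 20.7-fold from 0.654 ± 0.309 to 13.5 ± 3.65 TPM, and NR4A1 rose from 17.4 ± 4.57 to 59.9 ± 9.78 TPM. ZNF331, a zinc finger protein, rose 9.82-fold to 66.1 ± 13.3 TPM, and RGS2, which limits signalling by G protein-coupled receptors, 7.47-fold to 47.3 ± 14.9 TPM. The long non-coding RNA LINC00473 rose 7.24-fold to 68.5 ± 5.33 TPM and the secreted protein CRISPLD2 7.24-fold from 2.16 ± 0.146 to 15.6 ± 1.96 TPM. The kinase SGK1 rose 5.5-fold to 102 ± 32.5 TPM, and the surface proteins CD200, TM4SF1 and CD24 rose 5.84-fold, 4.62-fold and 4.25-fold. The transcription factor EGR1 fell from 19 ± 4.2 to 6.53 ± 0.29 TPM, and RGS4 from 5.1 ± 0.621 to 1.23 ± 0.393 TPM. The AP-1 subunits FOSL1 and JUN fell from 141 ± 15.9 to 54.5 ± 6.7 TPM and from 86.2 ± 5.3 to 44.5 ± 3.56 TPM.

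Of the 23 tested genes of the cAMP and CREB response, 15 rose and none fell with 1 uM ONO (17 rose adjusted over the list alone, list adjusted p = 5.2e-25). PDE4D, which breaks down cAMP, rose 4.39-fold from 2.18 ± 0.401 to 9.59 ± 0.594 TPM (n = 4). PDE4B rose 2.8-fold from 0.99 ± 0.104 to 2.77 ± 0.441 TPM, whereas PDE4A was at 1.71 ± 0.149 and 1.67 ± 0.202 TPM (adjusted p = 0.92). PTGER4, the gene of EP4 itself, was at 1.57 ± 0.0977 and 1.24 ± 0.0848 TPM (adjusted p = 0.19). Over the list of cAMP synthesis, breakdown and receptors 4 of 26 genes rose and 1 fell (7 and 2 adjusted over the list alone). Its list adjusted p was 0.0036, with adjusted p = 0.059 with an estimated correlation and at most 0.0067 with the other 4 alternatives.

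Of 23 negative regulators of inflammatory signalling, 10 rose and 2 fell with 1 uM ONO (10 and 4 adjusted over the list alone, list adjusted p = 3.1e-08). Of these 10, 6 are also on the cAMP or the glucocorticoid list. SOCS3, an inhibitor of cytokine receptor signalling, rose from 20.8 ± 1.41 to 41.7 ± 5.73 TPM (n = 4), and KLF4 from 1.56 ± 0.181 to 3.47 ± 0.994 TPM. Of 17 glucocorticoid-responsive genes 6 rose and none fell (7 adjusted over the list alone, list adjusted p = 6.6e-06), among them the clock gene PER1, from 11.3 ± 2.49 to 24.1 ± 2.05 TPM. PER1 is also on the cAMP and CREB list, so these lists are not independent. Of 13 inflammatory cytokines and chemokines 3 rose and 3 fell (4 and 3 adjusted over the list alone, list adjusted p = 0.34). IL6 rose from 4.48 ± 0.301 to 16.5 ± 6.21 TPM, IL11 from 41.4 ± 11.6 to 106 ± 9.69 TPM and CCL2 from 120 ± 16.4 to 162 ± 16.1 TPM. CCL5, IL16 and CSF1 fell.

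Immediate early genes went both ways with 1 uM ONO, with 6 of 24 higher and 10 lower (6 and 10 adjusted over the list alone). The list was lower at adjusted p = 0.039, with adjusted p = 0.66 with an estimated correlation and at most 0.046 with the other 4 alternatives. ATF3 and FOSL2 rose, and IER3, IER5 and KLF10 fell. Of 14 MAPK phosphatases and Sprouty family genes, which limit growth factor signalling, 3 rose and 5 fell (4 and 6 adjusted over the list alone, list adjusted p = 0.088). DUSP1, a phosphatase of stress-activated kinases, rose from 63.6 ± 8.77 to 104 ± 18.8 TPM (n = 4). The ERK phosphatases DUSP5 and DUSP6 fell, from 71.7 ± 7.03 to 41.3 ± 3.5 TPM and from 5.71 ± 0.529 to 2.44 ± 0.481 TPM. Of 27 cell cycle genes 5 fell and none rose (6 fell and 1 rose adjusted over the list alone, list adjusted p = 0.012). The mitotic kinases PLK1 and AURKA fell from 81.9 ± 3.8 to 61.8 ± 4.1 TPM and from 116 ± 10.3 to 89.2 ± 6.43 TPM.

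In limma's test 908 genes were called with 1 uM ONO, of which 52 were higher and 7 lower by at least 2-fold. In 735 of them, which were called on these same libraries, the 4 treated and 4 vehicle libraries did not overlap. The count was 2090 with the replicate block and 359 when only these 8 libraries were fitted. Vehicle replicate 3 stood apart from the other libraries, with short transcripts relatively higher and long ones lower, and every comparison with vehicle contains it.

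**Figure D1:**
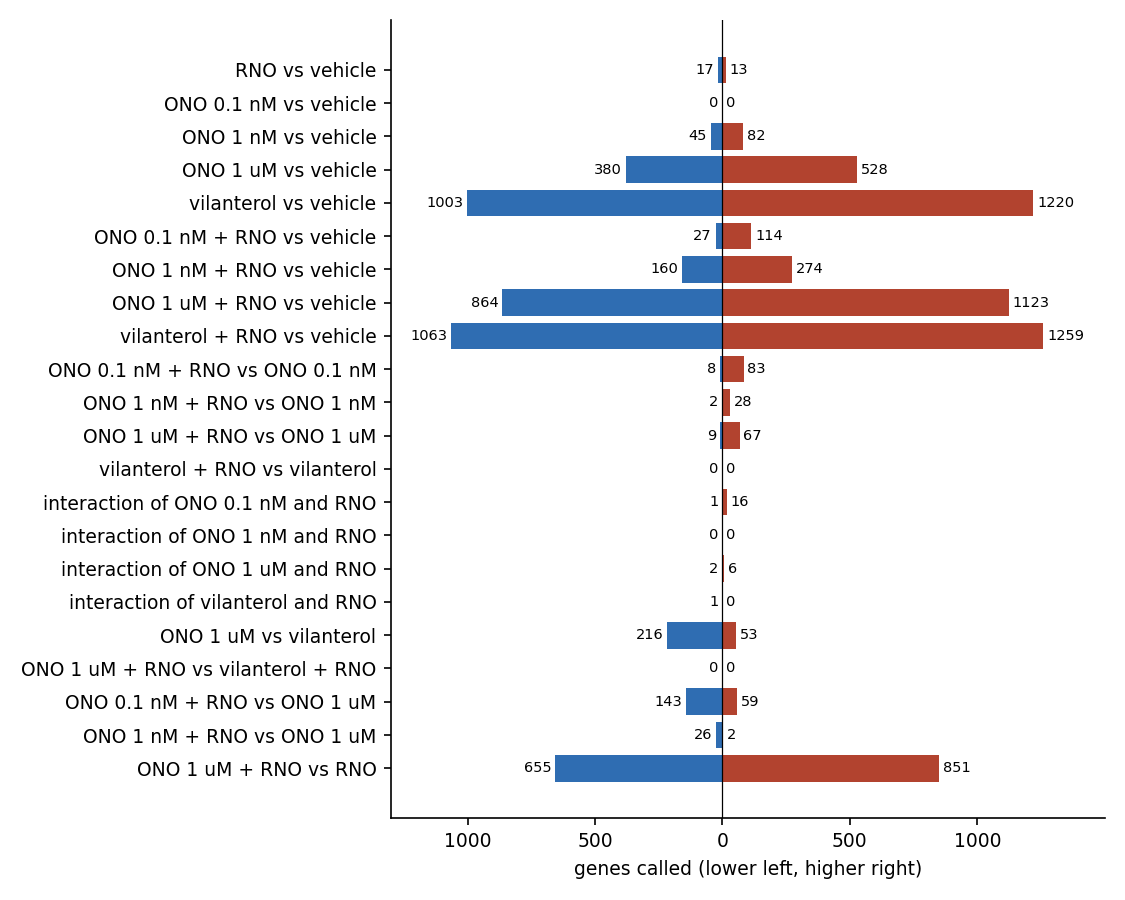
Number of genes called in each of the 22 comparisons (limma, adjusted p under 0.05, 12591 genes tested), with genes higher in the first-named treatment drawn to the right of 0 and genes lower drawn to the left. Vilanterol (2223) and vilanterol + RNO (2322) called the most genes against vehicle, and 0.1 nM ONO called 0.

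The response to ONO was graded with concentration. At 0.1 nM no gene was called in limma's test (736 had an unadjusted p under 0.05). The replicate block called 10 genes (4 when vehicle replicate 3 was also left out), and library weights, robust variances and both other scalings called 0 each. NR4A3, CRISPLD2 and SGK1 were at 1.66 ± 0.679, 2.34 ± 0.624 and 17.9 ± 1.1 TPM (SD, n = 4). At 1 nM 82 genes rose and 45 fell. NR4A3 rose 3.95-fold to 5.32 ± 0.708 TPM, NR4A2 3.87-fold to 2.53 ± 0.283 TPM and LINC00473 2.86-fold to 27 ± 2.55 TPM. PDE4D rose 2.22-fold to 4.85 ± 0.53 TPM and PDE4B 2.26-fold to 2.23 ± 0.207 TPM. EGR1 fell to 9.99 ± 1.82 TPM and RGS4 to 2.5 ± 0.511 TPM. Of the cAMP and CREB genes 6 of 23 rose at 1 nM (9 rose and 1 fell adjusted over the list alone). Their list adjusted p was 3e-08, with adjusted p = 0.067 with an estimated correlation and at most 4e-08 with the other 4 alternatives. Immediate early genes were lower as a list at 0.1 nM (0 of 24 fell, none adjusted over the list alone, adjusted p = 0.00071) and at 1 nM (4 fell, 8 fell and 1 rose adjusted over the list alone, adjusted p = 6e-04). Both calls were lost with an estimated correlation (adjusted p = 0.41 for each, at most 0.00074 with the other 4 alternatives).

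At 1 nM, 113 of the 127 called genes had no overlap between the groups. The count was 273 without vehicle replicate 2 and 194 without vehicle replicate 1, 1066 with the replicate block (612 when vehicle replicate 3 was also left out) and 28 with only these groups fitted. Over the 98 genes of the response score that were higher, the mean log2 level was 3.29 ± 0.06 in vehicle and 3.29 ± 0.1, 3.68 ± 0.05 and 4.43 ± 0.1 with 0.1 nM, 1 nM and 1 uM ONO (SD, n = 4). The difference from vehicle was 0 at 0.1 nM (exact permutation p = 0.971). It was 0.39 at 1 nM and 1.14 at 1 uM, higher in all 4 libraries (exact permutation p = 0.0286 for each, the smallest that 4 against 4 can give, adjusted 0.0421). Over the 4 genes of the score that were lower, the level fell by 0.63 at 1 nM and by 1.15 at 1 uM with the same p. At 0.1 nM the difference was -0.19 (exact permutation p = 0.0571, adjusted 0.0762).

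**Figure D2:**
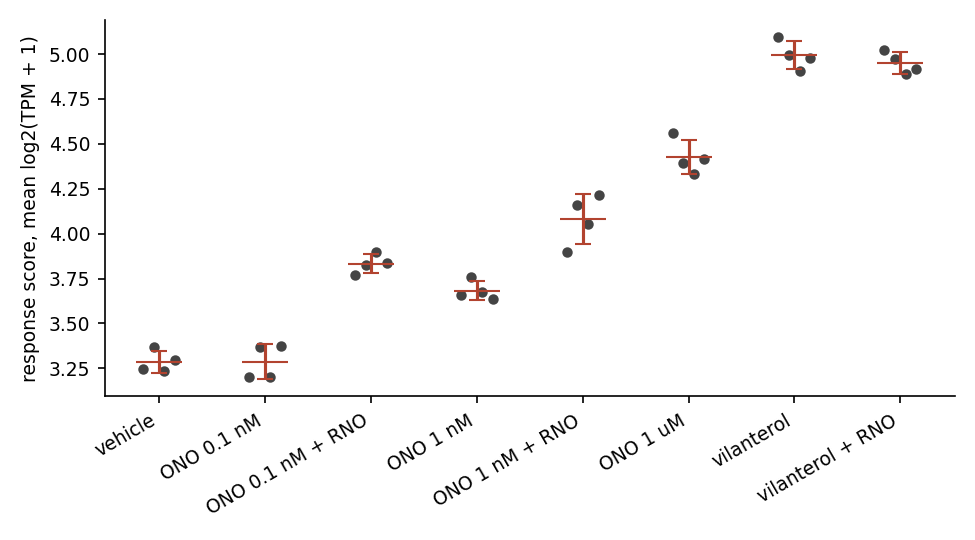
Response score per library (points, mean log2(TPM + 1) over the 98 genes chosen from 1 uM ONO + RNO against RNO) in the 8 groups outside that comparison, with group means and SD (bars, n = 4). With ONO alone the means were 3.29, 3.68 and 4.43 at 0.1 nM, 1 nM and 1 uM, with 0.1 nM and 1 nM ONO + RNO 3.83 and 4.08, and with vilanterol 4.99 without and 4.95 with RNO.

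Vilanterol raised 1220 and lowered 1003 genes. NR4A3 reached 73.3 ± 6.05 TPM (SD, n = 4), 54.3-fold over vehicle (adjusted p = 3e-21), NR4A2 25.8 ± 5.74 TPM, 39.4-fold, and ZNF331 110 ± 14.7 TPM, 16.4-fold. RGS2 rose 12.8-fold to 80.8 ± 21.8 TPM, SGK1 12.3-fold to 227 ± 60.9 TPM, CRISPLD2 11.8-fold to 25.4 ± 1.53 TPM and IL6 13.5-fold to 60.5 ± 19.2 TPM. PDE4D rose 6.92-fold to 15.1 ± 0.385 TPM and PDE4B 3.85-fold to 3.81 ± 0.571 TPM. TXNIP, which binds thioredoxin and responds to glucose, fell from 68 ± 5.85 to 15.1 ± 3.11 TPM, and EGR1 fell to 3.48 ± 0.381 TPM. PTGER4 fell to 1.06 ± 0.137 TPM (adjusted p = 0.0078).

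Of the 23 cAMP and CREB genes 18 rose with vilanterol and none fell (19 adjusted over the list alone, list adjusted p = 1.3e-26). Of the negative regulators of inflammatory signalling 14 of 23 rose and 2 fell (14 and 2 adjusted over the list alone, list adjusted p = 1.6e-12), including TNFAIP3, an inhibitor of NF-κB signalling (0.47 log2, adjusted p = 7.9e-05). Glucocorticoid-responsive genes rose in 9 of 17 (10 adjusted over the list alone, list adjusted p = 6.5e-09). Of 13 cytokines and chemokines 5 rose and 2 fell (5 and 3 adjusted over the list alone), a list higher at adjusted p = 0.02. That call was lost with an estimated correlation (adjusted p = 0.33) and with the replicate block (adjusted p = 0.065) and held with the other 3 alternatives (at most 0.025). CXCL2, a neutrophil chemokine, rose from 0.582 ± 0.184 to 2.55 ± 0.853 TPM (n = 4). Over cAMP synthesis, breakdown and receptors 6 of 26 rose and 2 fell (6 and 3 adjusted over the list alone, list adjusted p = 0.0054). With an estimated correlation it had adjusted p = 0.067, and at most 0.011 with the other 4 alternatives. Immediate early genes went both ways (10 of 24 higher and 9 lower, 10 and 10 adjusted over the list alone, list adjusted p = 0.92). So did MAPK phosphatases (4 of 14 higher and 5 lower, 5 and 6 adjusted over the list alone, list adjusted p = 0.88), and in both lists the median and mean were positive and the test pointed down. Of 27 cell cycle genes 8 fell and 2 rose (11 and 2 adjusted over the list alone, list adjusted p = 0.02).

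Of the 2223 genes called with vilanterol, 128 were higher and 12 lower by at least 2-fold, and 1600 had no overlap between the groups. The replicate block called 3931, and 912 were called with only these groups fitted.

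**Figure D3:**
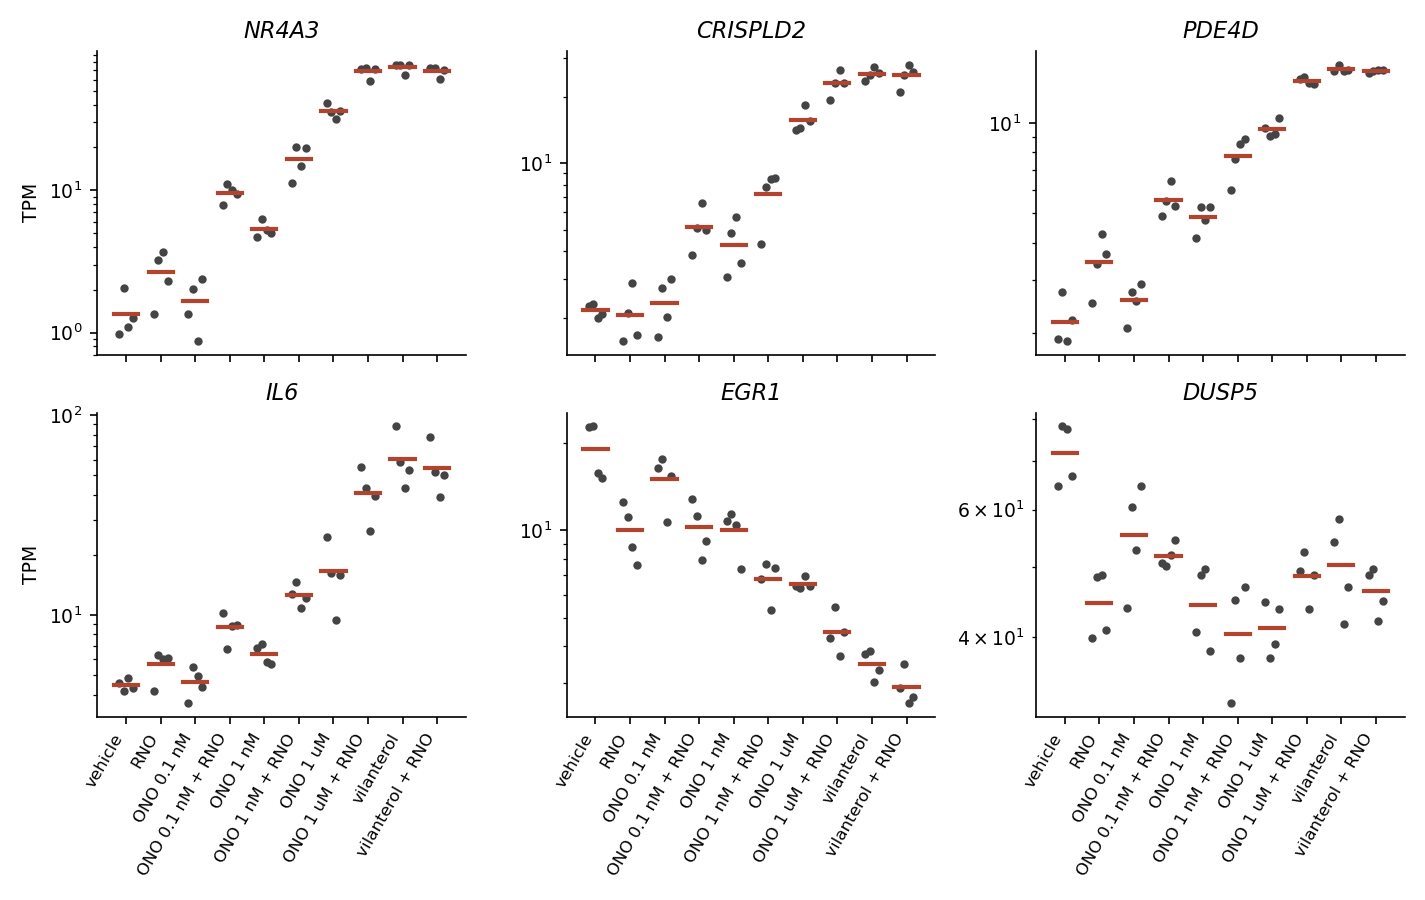
Levels per library (points, TPM on a log axis) of 6 genes in the 10 groups, with group means (horizontal bars, n = 4). NR4A3, CRISPLD2, PDE4D and IL6 had their highest mean with vilanterol (73.3, 25.4, 15.1 and 60.5 TPM), and EGR1 and DUSP5 had theirs in vehicle (19 and 71.7 TPM).

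Across the 12591 genes the log2 fold changes of 1 uM ONO and of vilanterol against the same vehicle libraries had Pearson r = 0.896 and Spearman rho = 0.807, over genes, which are not independent replicates. Shared vehicle libraries alone gave r = 0.501 and rho = 0.464 in simulated data without change (highest of 100 draws 0.566 and 0.484). The draws gave every group the same spread. The real vehicle libraries deviated more from their group mean (SD over genes 0.114 to 0.209) than those of 1 uM ONO (0.106 to 0.13) or vilanterol (0.103 to 0.129). The simulated values may therefore understate what shared vehicle libraries give. With separate vehicle libraries for each agonist, 2 apiece and after removal of replicate-number effects, r was 0.698 (0.68 to 0.712 over 6 splits) and rho 0.453 (0.397 to 0.509). Both agonists raised 503 genes and lowered 318, and with these shared libraries no gene was called in opposite directions. Independent lists would share 51.2 and 30.3, but the shared vehicle libraries can add to the overlap. In the splits with separate vehicle libraries a mean of 1410 genes rose with ONO (668 to 2290), 2050 with vilanterol (1350 to 2840) and 703 with both (569 to 841). For genes that fell the means were 1160 (601 to 1820), 1910 (1260 to 2560) and 506 (412 to 588), and a mean of 13 genes was called in opposite directions (4 to 33). Replicate-number effects were subtracted before these fits, which did not allow for their estimation. The counts are therefore not comparable with those of the main model. Tested directly, 53 genes were higher and 216 lower with 1 uM ONO than with vilanterol. NR4A3 was at 0.494-fold and PDE4D at 0.635-fold of the vilanterol level (adjusted p = 0.00063 and 0.00019), IL6 at 0.273-fold, SGK1 at 0.448-fold, DUSP1 at 0.478-fold and CXCL2 at 0.381-fold. TXNIP and ARRDC4, arrestin-like proteins that respond to glucose, were higher with ONO, at 46.2 ± 9.29 against 15.1 ± 3.11 TPM and at 9.53 ± 0.967 against 5.53 ± 0.467 TPM (n = 4). Of the 269 called genes 252 had no overlap between the groups. The count became 157 without replicate 2 of 1 uM ONO, 856 with the replicate block and 454 with library weights. The higher response score differed by -0.57 (exact permutation p = 0.0286, adjusted 0.0421) and the lower one by 0.47 (exact permutation p = 0.0571, adjusted 0.0762).

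**Figure D4:**
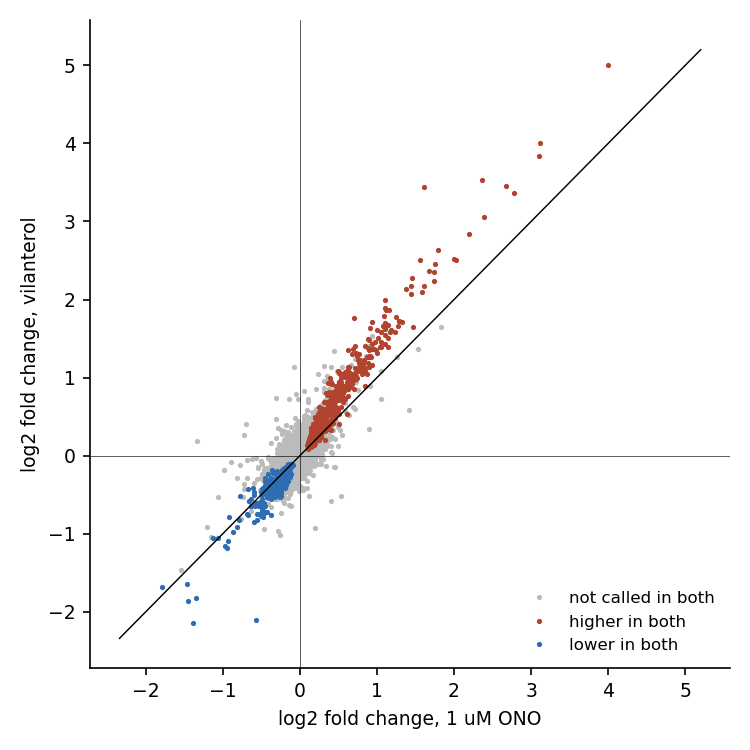
Log2 fold change against vehicle of each of the 12591 genes tested, with 1 uM ONO on the x axis and vilanterol on the y axis, genes called in both comparisons coloured (503 higher, 318 lower) and the line of equal change drawn. Over the 2223 genes called with vilanterol the median ratio of the ONO change to the vilanterol change was 0.622.

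RNO alone changed 30 genes, 13 higher and 17 lower, none by 2-fold on the log2 scale used. PDE4B rose 1.92-fold from 0.99 ± 0.104 to 1.9 ± 0.29 TPM (SD, n = 4, adjusted p = 0.0044) and PDE4D 1.58-fold to 3.45 ± 0.727 TPM (adjusted p = 0.022). PPP1R3C, a glycogen-targeting phosphatase subunit, rose 1.63-fold to 5.93 ± 0.725 TPM, and the growth factors FGF9 and WNT5A also rose. EGR1 fell to 10 ± 2.22 TPM, 0.525-fold (adjusted p = 0.0051), and DUSP5 to 44.6 ± 4.75 TPM, 0.622-fold. SPRY4, an inhibitor of growth factor signalling, fell to 1.5 ± 0.102 TPM, 0.565-fold. PDE4A was at 1.77 ± 0.237 TPM and NR4A3 at 2.65 ± 1.05 TPM (adjusted p = 0.92 and 0.17). Of 24 immediate early genes 2 fell (12 adjusted over the list alone) and none rose, a list lower at adjusted p = 4.9e-11. With an estimated correlation it had adjusted p = 0.058, and at most 5.9e-11 with the other 4 alternatives. Of 14 MAPK phosphatases and Sprouty genes 2 fell (3 adjusted over the list alone, list adjusted p = 0.014, adjusted p = 0.41 with an estimated correlation and at most 0.049 with the other 4 alternatives). Of the cAMP and CREB genes 2 of 23 rose (6 rose and 3 fell adjusted over the list alone, list adjusted p = 0.22), and with the replicate block 5 rose and 2 fell.

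Of the 30 genes called with RNO, 28 had no overlap between the groups. The count was 8 without RNO replicate 4, 17 without RNO replicate 2, 13 without vehicle replicate 3 and 57 without vehicle replicate 1. It was 643 with the replicate block (252 when vehicle replicate 3 was also left out), 14 with libraries rescaled to equal totals and 0 with only these groups fitted.

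RNO together with 0.1 nM ONO raised 114 genes and lowered 27 against vehicle. NR4A3 reached 9.62 ± 1.33 TPM (SD, n = 4), 7.13-fold over vehicle and 5.81-fold over 0.1 nM ONO alone (adjusted p = 3e-10 and 2.5e-09). LINC00473 reached 35 ± 4.94 TPM, TM4SF1 122 ± 23 TPM, SGK1 45 ± 5.46 TPM and PDE4D 5.54 ± 0.646 TPM. Of the cAMP and CREB genes 9 of 23 rose (11 adjusted over the list alone, list adjusted p = 3.6e-16). Of the negative regulators of inflammatory signalling 8 of 23 rose (9, with 1 lower, adjusted over the list alone, list adjusted p = 3.9e-09), and of the glucocorticoid-responsive genes 4 of 17 (5 adjusted over the list alone, list adjusted p = 0.0025). Against 0.1 nM ONO alone 83 genes were higher and 8 lower, the latter including HJURP and PSRC1, which act in mitosis. The interaction test asked whether RNO changed a gene more with than without 0.1 nM ONO, and called 16 genes higher and 1 lower. NR4A3 (1.42 log2, adjusted p = 0.0062), TM4SF1 (1.05, 2e-04), IL11 (1.37, 0.038), SOCS3 (0.95, 0.0022), CCL2 (0.95, 0.0022) and KRT17 (0.63, 0.038) were among the 16. TP53INP1, a p53-induced gene, was the gene that was lower (-0.28, adjusted p = 0.038).

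Of the 141 genes called against vehicle 132 had no overlap. The replicate block called 645, only these groups fitted called 37, and with libraries rescaled to equal totals 143 were higher and 11 lower. Of the 91 genes called against 0.1 nM ONO 90 had no overlap, and the count was 60 without replicate 3 of 0.1 nM ONO, 325 with the replicate block, 166 with library weights and 47 with only these groups fitted. The interaction count of 17 was reached by 5 of 100 drawn splits of the libraries. It was 7 without vehicle replicate 2, RNO replicate 4, 0.1 nM ONO replicate 1 or 0.1 nM ONO + RNO replicate 3, and 8 without RNO replicate 1, 0.1 nM ONO replicate 3 or 0.1 nM ONO + RNO replicate 4. It was 9 without 0.1 nM ONO + RNO replicate 2, 10 without vehicle replicate 4 and 34 without RNO replicate 3. The replicate block gave 324, libraries rescaled to equal totals 5 and only these groups fitted 1.

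At 1 nM ONO the addition of RNO raised 28 genes and lowered 2. NR4A3 rose 3.1-fold from 5.32 ± 0.708 to 16.5 ± 4.26 TPM (SD, n = 4, adjusted p = 2.5e-05). RGS2 rose from 15.6 ± 3.84 to 34.3 ± 6.88 TPM, SGK1 from 34.7 ± 5.19 to 71.9 ± 4.99 TPM and PDE4D from 4.85 ± 0.53 to 7.75 ± 1.3 TPM, and HJURP and HYLS1 fell. Against vehicle the combination raised 274 and lowered 160 genes, with 11 of 23 cAMP and CREB genes higher (13 adjusted over the list alone, list adjusted p = 1.8e-20). No gene was called in the interaction by limma (1108 had an unadjusted p under 0.05), and 3 were called with library weights. Without 1 nM ONO replicate 1 it called 6, without 1 nM ONO + RNO replicate 1 it called 4, and without 1 nM ONO replicate 3 or vehicle replicate 4 it called 1. Of the 30 genes 29 had no overlap, and of the 434 against vehicle 376, with 144 called with only these groups fitted. The count of 30 was 151 with the replicate block, 80 with library weights and 9 with only these groups fitted. It was 18, 14 and 11 without replicates 1, 3 and 4 of 1 nM ONO and 48, 12, 15 and 11 without replicates 1, 2, 3 and 4 of 1 nM ONO + RNO.

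At 1 uM ONO the addition of RNO raised 67 genes and lowered 9. IL6 rose 2.48-fold from 16.5 ± 6.21 to 41 ± 11.9 TPM (SD, n = 4, adjusted p = 0.0017) and NR4A3 1.9-fold from 36.2 ± 3.94 to 68.6 ± 6.72 TPM (adjusted p = 0.0071). DUSP1 rose 1.7-fold to 178 ± 25 TPM, the small GTPase RHOB 1.58-fold, PDE4D 1.44-fold and CD274, the immune checkpoint ligand PD-L1, 1.54-fold from 4.15 ± 0.388 to 6.38 ± 0.635 TPM. HJURP, BORA and PSRC1, which act in mitosis, were among the 9 that fell. The interaction called 6 genes higher and 2 lower, and 7 and 1 with libraries rescaled to equal totals. Among those higher were PLAUR, the urokinase receptor (0.73 log2, adjusted p = 1.7e-05), DUSP5 (0.91, 0.013), MAP2K3, NR2F2 and SOWAHC, and TP53INP1 and ZFP37 were lower. RNO alone lowered DUSP5, and with 1 uM ONO DUSP5 was at 41.3 ± 3.5 TPM without and 48.6 ± 3.62 TPM with RNO.

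Of the 76 genes that RNO changed at 1 uM ONO 67 had no overlap. The count was 464 with the replicate block, 174 with library weights and 24 with only these groups fitted. It was 37 and 39 without replicates 2 and 4 of 1 uM ONO and 45 and 47 without replicates 1 and 2 of 1 uM ONO + RNO. The interaction count of 8 was reached by 5 of 100 drawn splits. It was 32 and 1 without replicates 1 and 2 of 1 uM ONO, 16, 17 and 1 without RNO replicates 1, 3 and 4, 18 and 25 without vehicle replicates 1 and 3, and 15 without replicate 1 of 1 uM ONO + RNO. Library weights gave 35, no filter 14 and only these groups fitted 2.

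Against vehicle the combination of 1 uM ONO and RNO raised 1123 and lowered 864 genes (1134 and 573 with libraries rescaled to equal totals), and against RNO alone 851 and 655. NR4A3 was 50.9-fold, IL6 9.15-fold and PDE4D 6.33-fold over vehicle, the last at 13.8 ± 0.375 TPM (n = 4). EGR1 fell to 4.48 ± 0.732 TPM and TXNIP to 28.4 ± 5.76 TPM. Of the cAMP and CREB genes 17 of 23 rose against vehicle and none fell (17 adjusted over the list alone, list adjusted p = 7.1e-26). Against vehicle 1441 of the 1987 genes had no overlap, 3739 were called with the replicate block and 778 with only these groups fitted. Against RNO 1311 of the 1506 had no overlap and 2564 were called with the replicate block.

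Adding RNO to vilanterol changed no gene in limma's test (180 had an unadjusted p under 0.05), and 0 were called with the replicate block and with every other alternative fitted. NR4A3 was at 73.3 ± 6.05 TPM with vilanterol and 68.9 ± 5.34 TPM with both (SD, n = 4). The higher response score was 4.99 ± 0.08 and 4.95 ± 0.06 (difference -0.04, exact permutation p = 0.457, adjusted 0.474). The difference was -0.07 without vilanterol replicate 3 or vilanterol + RNO replicate 1, -0.02 without vilanterol + RNO replicate 3 and -0.01 without vilanterol replicate 1. Within pairs of equal replicate number it was lower with RNO in all 4 (-0.068 to -0.014), as were NR4A3 (-0.13 to -0.06 log2), IL6 (-0.17 to -0.08) and EGR1 (-0.29 to -0.11), examined after their values were seen, and an exact test of 4 pairs cannot give a p under 0.125. Vilanterol + RNO raised 1259 and lowered 1063 genes against vehicle, and 1384 and 650 with libraries rescaled to equal totals. Of the cAMP and CREB genes 17 of 23 rose (17 adjusted over the list alone, list adjusted p = 1.3e-23). Of the 2322 genes 1636 had no overlap, 4029 were called with the replicate block and 960 with only these groups fitted. The interaction called 1 gene, PPM1D, a p53-induced phosphatase that RNO alone raised from 15.5 ± 0.177 to 18.3 ± 0.888 TPM. It called 0 with libraries rescaled to equal totals or with only these groups fitted. It called 2 without RNO replicate 1 or vilanterol replicate 1. It called 0 without vehicle replicate 2, 3 or 4, RNO replicate 2, 3 or 4, vilanterol replicate 2 or 4, or vilanterol + RNO replicate 2 or 4. With RNO present, 1 uM ONO and vilanterol differed in no gene by limma (306 at an unadjusted p under 0.05, 4 with the replicate block), against 269 without RNO, and the difference between these counts was not tested. Without 1 uM ONO + RNO replicate 1 or vilanterol + RNO replicate 3, as with a pseudocount of 0.1, a mean of at least 5 TPM, rescaled totals or library weights, 1 gene was called.

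Low concentrations of ONO with RNO were also set against 1 uM ONO alone. With 0.1 nM ONO + RNO 59 genes were higher and 143 lower, and 98 and 100 with libraries rescaled to equal totals. NR4A3 was at 9.62 ± 1.33 against 36.2 ± 3.94 TPM (SD, n = 4), 0.266-fold (adjusted p = 2.4e-08), CRISPLD2 at 0.329-fold and KRT17 at 0.486-fold. RGS4 and JUN, which 1 uM ONO lowered, were 2.83-fold and 1.54-fold higher. With 1 nM ONO + RNO 2 genes were higher and 26 lower, among them NR4A3 at 0.456-fold and CRISPLD2 at 0.467-fold (adjusted p = 0.00079 for each). The higher response score stood 0.55 over vehicle with 0.1 nM ONO + RNO and 0.79 with 1 nM ONO + RNO, 47.8% and 69.7% of the 1.14 with 1 uM ONO. ONO at 1 nM alone reached 34.6% and vilanterol 150%. Both combinations were lower than 1 uM ONO (-0.59 and -0.34, in all 4 libraries, exact permutation p = 0.0286, adjusted 0.0421). Each was higher than the same ONO concentration without RNO (0.55 and 0.4, same p). The score with 0.1 nM ONO + RNO was 0.15 above that with 1 nM ONO alone (exact permutation p = 0.0286, adjusted 0.0421, and 0.0333 to 0.08 over 7 alternatives).

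Of the 202 genes called between 0.1 nM ONO + RNO and 1 uM ONO 193 had no overlap, and the count was 127 without replicate 1 of 0.1 nM ONO + RNO and 688 with the replicate block. The 28 genes called between 1 nM ONO + RNO and 1 uM ONO all had no overlap. Their count was 8 without replicate 1 of 1 nM ONO + RNO, 11 and 17 without replicates 1 and 3 of 1 uM ONO, 14 with libraries rescaled to equal totals and 1 with only these groups fitted.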

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

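Of the tests of vehicle replicate 3 (length, scaling, swap), of vilanterol with RNO and of MIR6723, those of vehicle replicate 3, of the level reached with vilanterol alone, of pairs with vilanterol and of short transcripts were chosen after the result was seen.

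Vehicle replicate 3 had the largest column total (1091466) and the largest SD of deviations from its group mean (0.209, 0.099 to 0.169 in the other 39 libraries). After median ratio scaling the SD was 0.208 (0.0989 to 0.169 in the others). A scaling factor shifts most log2 values alike and an SD over genes removes a common shift, so this cannot test scaling of the library. Over genes its median offset from the mean of all libraries was 0.004 log2. Its distance from each of the 9 other groups was 1.41 to 2.11 times the highest among that group's own libraries (SD over genes of the difference from means of 3 libraries). A library distorted by transcript length (below) would lie far from every group, its own included, so this distance cannot test a swap. Its response score, -0.07 from the mean of the other 3 vehicle libraries, argues against a swap with an agonist group whose score differs from vehicle. The score cannot test a swap with RNO or 0.1 nM ONO, whose higher scores lay 0.02 and 0 from the vehicle mean. Its deviations followed transcript length (Spearman rho -0.586 over 95% of the tested genes, -0.3 to 0.413 in the other libraries), from 0.16 log2 in the fifth of genes with a median length of 1493 bases to -0.18 at 7572.5 bases. The vehicle mean includes this library, which pushes the other 3 vehicle libraries the opposite way (rho 0.194 to 0.413). Outside the vehicle group rho lay between -0.3 and 0.267. A loss of long transcripts in this library may be a cause and stays open, and the design gave no biological explanation to test.

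No gene was called when RNO was added to vilanterol by limma (180 at an unadjusted p under 0.05, 0 with the replicate block). A larger spread between the vilanterol libraries is argued against, since their median residual SD was 0.894 times that of the other groups. The response to vilanterol alone may already be at its upper level: over the 83 genes that RNO raised at 0.1 nM ONO it was 0.09 log2 above 1 uM ONO + RNO, and adding RNO changed them by a median of 0 (-0.02 to 0.05 by library), against 0.31 at 1 uM ONO. RNO may also not have acted in these libraries, since the 6 genes called with RNO alone and not with vilanterol changed by a median of 0 (-0.01 to 0.05 by library), against 0.21 with RNO alone. The higher response score was lower with RNO in all 4 pairs of equal replicate number (-0.068 to -0.014). Of the tested genes 16.8% changed in 1 direction in all 4 pairs, against 11.1% to 14% with the signs of pairs exchanged in other ways. With 8 ways in all, no p under 0.125 was possible, so these values do not settle whether RNO acted. Both explanations stay open. Of the 24 genes called with RNO alone and with vilanterol, 23 went in the same direction. Both comparisons share the vehicle libraries, which by itself favours a common direction, so this count does not test whether RNO and vilanterol act alike.

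MIR6723 alone held 24.2% to 27.8% of each column total, and MIR4461 4.25% to 7.04%. Of the 31-base words of the MIR6723 transcript 81.4% occur in MT-CO1 on the opposite strand, so shared mitochondrial sequence may account for its level. Of those of MIR4461 only 4.55% (2 of 44) occur in an annotated mitochondrial transcript. Exact words within single annotated transcripts miss mitochondrial sequence across or between genes, so this account was neither shown nor excluded for MIR4461. Of the 50 highest entries, 42 had an annotated length and 7.14% of these (3) were under 200 bases, against 0.621% (91 of 14652) of all. These 3 include MIR6723 (89 bases) and MIR4461 (74 bases), the entries in question, so the share cannot test length scaling of short transcripts. Neither shared mitochondrial sequence nor length scaling was excluded, and no biological explanation was tested.

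For a library far from the other 3 of its group (by Dixon's test), 214 groups were examined and 15 passed, where chance flags about 1 in 20 groups, or 10.7. The column total of 1 uM ONO + RNO replicate 2 was 961315, against 995686 to 998062. The lower response score of 1 uM ONO replicate 3 was 4.14, against 4.67 to 4.76. In vehicle replicate 2 DUSP1 was at 76.7 TPM (58.8 to 59.5 in the others), DUSP6 at 6.49 (5.35 to 5.55) and NR4A2 at 1.11 (0.467 to 0.565), and in vehicle replicate 3 ID3 was at 6.83 (4.4 to 4.7). With 1 nM ONO NR4A2 was at 2.11 in replicate 3 (2.64 to 2.71) and PDE4B at 1.92 in replicate 2 (2.32 to 2.35). SGK1 was at 19.5 in 0.1 nM ONO replicate 3 (17.2 to 17.4). With 1 uM ONO EGR1 was at 6.96 in replicate 3 (6.32 to 6.43) and PDGFB at 5.92 in replicate 4 (5.11 to 5.2). NR4A3 was at 58.5 in 1 uM ONO + RNO replicate 3 (71.5 to 72.6) and at 64.2 in vilanterol replicate 3 (75.7 to 76.6). In vilanterol replicate 1 CXCL2 was at 3.83 (2.06 to 2.22) and SLC7A5 at 565 (493 to 499).

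The effect of RNO differed with and without ONO or vilanterol in 17 genes for 0.1 nM ONO, 8 for 1 uM ONO and 1 for vilanterol, each by a test of the interaction. As many genes were called by 5 of 100 drawn splits for 0.1 nM ONO (highest other 1982), 5 of 100 for 1 uM ONO (highest other 67) and 14 of 100 for vilanterol (highest other 59). Chance was therefore not excluded for these 3 counts. Every pair of equal replicate number had r above 0.1 only for 0.1 nM ONO, where the 8 draws that part all pairs had a highest other of 63. For 1 uM ONO and vilanterol the median r was 0.281 and 0.235 and the lowest 0.0686 and 0.0321, so pairing was not absent there. The split with 1982 genes called several times the real count, which points to a structure of the samples beyond their groups, as do 67 and 59. For 1 nM ONO the interaction called 0 genes by limma (1108 at an unadjusted p under 0.05, 213 with the replicate block), 100 of 100 splits called as many and the highest other called 23.

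Chance was not excluded for RNO against vehicle, where 2 of 35 splits of the 8 libraries called at least the real 30 genes. The other called 835 and set replicates 1 and 2 against 3 and 4. The same kind of split called 1071 for 0.1 nM ONO against vehicle, where 35 of 35 called at least the real 0 (limma, 736 at an unadjusted p under 0.05, 10 with the replicate block, 4 without vehicle replicate 3 as well). A count of 835 against 30, and of 1071 where the real split called 0, points to a structure of the samples by replicate number. Among the 8 splits that part all pairs of equal number, the highest other was 0 for RNO and 1 for 0.1 nM ONO. For vilanterol + RNO against vilanterol and for 1 uM ONO + RNO against vilanterol + RNO the real counts were 0 by limma (180 and 306 at an unadjusted p under 0.05, 0 and 4 with the replicate block), so 35 of 35 splits called as many, with highest others of 1 and 0.

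For the other counts only the real split, 1 of 35, called as many genes, the smallest share these splits can give. The shares were not adjusted over the comparisons. Libraries paired by number in most of these comparisons, and the 8 splits that part all pairs are too few to exclude chance. Against vehicle the real count and the highest other were 127 and 3 for 1 nM ONO, 908 and 236 for 1 uM ONO, 2223 and 499 for vilanterol, 141 and 7 for 0.1 nM ONO + RNO, 434 and 76 for 1 nM ONO + RNO, 1987 and 678 for 1 uM ONO + RNO, and 2322 and 723 for vilanterol + RNO. Among the splits parting all pairs the highest others were 5 for 1 uM ONO, 29 for vilanterol, 3 for 1 uM ONO + RNO and 7 for vilanterol + RNO. For RNO added to 0.1 nM, 1 nM and 1 uM ONO they were 91 and 2, 30 and 2, and 76 and 7. For 1 uM ONO against vilanterol they were 269 and 15, for 0.1 nM and 1 nM ONO + RNO against 1 uM ONO 202 and 0 and 28 and 0, and for 1 uM ONO + RNO against RNO 1506 and 140.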

How the results depend on the processing

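Library weights, the replicate block without vehicle replicate 3, and gene lists with rescaled libraries were chosen after results had been seen, and the other alternatives before the data were examined. An alternative at the level of transcripts was not run, because the table holds genes. Where a cause is not named below, the cause was not tested. Of the 22 counts of called genes none moved by over 1.5 times with median ratio scaling, a pseudocount of 2 or robust variances.

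The replicate block removes variance between replicate numbers and gave 643 genes for RNO, 10, 1066 and 2090 for 0.1 nM, 1 nM and 1 uM ONO, 3931 for vilanterol, and 645, 1259, 3739 and 4029 for these 4 agonist treatments with RNO, each against vehicle. It gave 325, 151 and 464 for RNO added to 0.1 nM, 1 nM and 1 uM ONO, 324, 213, 473 and 31 for the interactions (0.1 nM, 1 nM and 1 uM ONO, vilanterol), 856 for 1 uM ONO against vilanterol and 4 with RNO in both. For 0.1 nM and 1 nM ONO + RNO against 1 uM ONO it gave 688 and 183, and for 1 uM ONO + RNO against RNO 2564. Without vehicle replicate 3 the block gave 252, 4, 612, 1803, 3377, 432 and 1310 for RNO, 0.1 nM, 1 nM and 1 uM ONO, vilanterol, and 0.1 nM and 1 nM ONO + RNO against vehicle, and 442, 184, 683 and 36 for the interactions.

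With only the groups compared, fewer libraries estimated the variance. Against vehicle the counts were 0 for RNO, 28 and 359 for 1 nM and 1 uM ONO, 912 for vilanterol, and 37, 144, 778 and 960 for 0.1 nM, 1 nM and 1 uM ONO and vilanterol with RNO. For RNO added to 0.1 nM, 1 nM and 1 uM ONO they were 47, 9 and 24, for the interactions of 0.1 nM ONO, 1 uM ONO and vilanterol 1, 2 and 0, and for 1 nM ONO + RNO against 1 uM ONO 1. Library weights gave 166, 80 and 174 for RNO added to 0.1 nM, 1 nM and 1 uM ONO, 3 and 35 for the interactions of 1 nM and 1 uM ONO, 454 for 1 uM ONO against vilanterol and 1 with RNO in both. Rescaling to equal totals gave 14 for RNO, 5 and 0 for the interactions of 0.1 nM ONO and vilanterol, 14 for 1 nM ONO + RNO against 1 uM ONO, and 1 for 1 uM ONO + RNO against vilanterol + RNO, which was also 1 with a pseudocount of 0.1 and with a mean of at least 5 TPM. Without a filter the interaction of 1 uM ONO gave 14.

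Without single libraries the counts ranged as follows against vehicle: RNO 8 to 57, 0.1 nM ONO 0 to 0, 1 nM ONO 92 to 273, 1 uM ONO 684 to 1142, vilanterol 1796 to 2702, and with RNO 96 to 204, 321 to 513, 1495 to 2477 and 1851 to 2769. For RNO added to an agonist they ranged from 60 to 84, 11 to 48, 37 to 77 and 0 to 0, and for the interactions from 7 to 34, 0 to 6, 1 to 32 and 0 to 2. They ranged from 157 to 228 for 1 uM ONO against vilanterol, 0 to 1 with RNO in both, 127 to 165 and 8 to 30 for 0.1 nM and 1 nM ONO + RNO against 1 uM ONO, and 1200 to 1391 against RNO. None of the 28 score differences moved by more than the larger group SD, and the sign varied only for the higher score of 0.1 nM ONO against vehicle (-0.03 to 0.03). Among those that did not pass, 6 others also moved by 1.5 times or more: the higher score of RNO added to vilanterol (-0.04, -0.07 to -0.01) and the lower scores of 0.1 nM ONO against vehicle (-0.19, -0.23 to -0.12), of 0.1 nM ONO + RNO against 1 nM ONO (0.17, 0.08 to 0.26), of RNO added to 1 nM ONO (-0.3, -0.39 to -0.2) and vilanterol (-0.11, -0.15 to -0.04) and of 1 nM ONO + RNO against 1 uM ONO (0.21, 0.07 to 0.31). No p was computed for scores without single libraries. Within pairs of equal replicate number, examined after results had been seen, no score could pass (lowest possible p 0.125 with 4 pairs). Of the differences that did not pass, the lower scores of 0.1 nM ONO against vehicle (-0.426 to -0.009) and of RNO added to 1 nM ONO (-0.443 to -0.056) also had 1 sign in all 4 pairs.

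The higher score of 0.1 nM ONO + RNO against 1 nM ONO (0.15) kept its direction and was no longer past the threshold with a pseudocount of 2 (0.15, adjusted p = 0.08), without a filter (0.14, 0.0667) and with a mean of at least 5 TPM (0.16, 0.08). The lower score of 1 uM ONO against vilanterol passed the threshold with a pseudocount of 0.1 (0.51, adjusted p = 0.04), without a filter (0.73), rescaled (0.73) and with genes of any fold change (0.1). Without a filter (adjusted p = 0.0348) it also passed for 0.1 nM ONO against vehicle (-0.21), RNO added to 0.1 nM (-0.21) and 1 nM ONO (-0.29), and 1 nM ONO + RNO against 1 uM ONO (0.3). Rescaled (0.0364) it passed for RNO added to 1 nM ONO (-0.33) and for 1 nM ONO + RNO against 1 uM ONO (0.26). With genes of any fold change (0.0333) it passed for RNO added to 0.1 nM (-0.06) and 1 nM ONO (-0.06) and for 1 nM ONO + RNO against 1 uM ONO (0.06). That of 0.1 nM ONO + RNO against 1 nM ONO reversed (-0.02, main value 0.17). The correlation of the 2 agonists' changes fell to 0.698 with separate vehicle libraries, which removes the shared controls, leaves 2 vehicle libraries for each agonist and was run after removal of replicate-number effects.

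Of 477 results of single genes that the rule or the text names, none reversed. The number no longer past the threshold was 14 with a pseudocount of 0.1, 10 without a filter, 40 rescaled, 1 with median ratios, 7 with robust variances, 11 with library weights and 121 with only the groups compared. It was 434 of the values without single libraries (3698 kept their side and 4 passed it). The number newly past it was 15 with the replicate block, 8 with the block without vehicle replicate 3, 1 with a pseudocount of 0.1 and 1 with library weights. Of 180 list tests 39 were no longer past it with an estimated correlation, 2 with a pseudocount of 0.1, 7 with the block (5 newly past) and 8 rescaled (9 newly past). Depth is unknown, so no limit from counting could be given.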

Other observations

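The tests of the graded genes in RNO alone and of the size of the ONO response were chosen after results had been seen, and the gene list tests were chosen before the data were examined. Of 19 tested genes of the unfolded protein and ATF4 response, which supports amino acid supply under stress, 6 rose and 3 fell with 1 uM ONO (7 and 3 adjusted over the list alone, list adjusted p = 0.0036). That call was lost with an estimated correlation (adjusted p = 0.067, at most 0.01 with the other 4 alternatives). With vilanterol 7 rose and 3 fell (7 and 3 adjusted over the list alone, list adjusted p = 0.00075). The amino acid transporter SLC7A5 rose from 213 ± 28.1 TPM in vehicle to 388 ± 40.1 TPM with 1 uM ONO and 513 ± 35 TPM with vilanterol (SD, n = 4), and DDIT4, an inhibitor of mTORC1, from 16.6 ± 1.33 to 42.1 ± 9.14 and 55.4 ± 12.6 TPM. Of 23 TGF-beta and BMP genes 6 rose and 1 fell with 1 uM ONO (6 and 2 adjusted over the list alone, list adjusted p = 0.039, adjusted p = 0.28 with an estimated correlation and at most 0.043 with the other 4 alternatives). With vilanterol 8 rose and 1 fell (10 and 2 adjusted over the list alone, list adjusted p = 6.2e-05). ID3, an inhibitor of differentiation, rose from 5.09 ± 1.17 to 11.2 ± 1.74 and 17.5 ± 3.01 TPM, and TGIF1, a repressor of SMAD signalling, from 28.4 ± 2.97 to 48 ± 2.71 and 70.1 ± 3.56 TPM. Of 22 growth factors and receptors 3 rose and 4 fell with 1 uM ONO (5 and 4 adjusted over the list alone, list adjusted p = 0.79, where the median was positive and the test pointed down). With vilanterol 8 rose and 2 fell (11 and 3 adjusted over the list alone, list adjusted p = 0.031, adjusted p = 0.45 with an estimated correlation and at most 0.036 with the other 4 alternatives). The neurotrophin BDNF rose from 12.2 ± 1.79 to 27.8 ± 2.69 and 40.6 ± 2.43 TPM, and PDGFB fell from 11 ± 1.36 to 5.34 ± 0.386 and 5.94 ± 0.415 TPM.

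Of 22 cholesterol synthesis genes 4 rose with 1 uM ONO (4 adjusted over the list alone, list adjusted p = 0.015, adjusted p = 0.57 with an estimated correlation and at most 0.016 with the other 4 alternatives). With vilanterol 10 rose (12, with 1 lower, adjusted over the list alone, list adjusted p = 0.00012, adjusted p = 0.33 with an estimated correlation and at most 0.00012 with the other 4 alternatives). CYP51A1 rose from 197 ± 6.06 to 219 ± 6.44 and 252 ± 5.8 TPM (n = 4). Of 18 circadian clock genes 3 rose with 1 uM ONO (4 adjusted over the list alone, list adjusted p = 0.02, adjusted p = 0.27 with an estimated correlation and at most 0.022 with the other 4 alternatives). With vilanterol 4 rose and 1 fell (4 and 1 adjusted over the list alone, list adjusted p = 0.078). NFIL3, a repressor within the clock, rose from 12.1 ± 1.67 to 21.7 ± 3.41 and 27.2 ± 3.48 TPM. Of 25 YAP and TEAD targets 2 rose and 5 fell with 1 uM ONO (4 and 5 adjusted over the list alone, list adjusted p = 0.79), and 6 and 3 with vilanterol (11 and 5 adjusted over the list alone, list adjusted p = 0.072). The Hippo kinase gene LATS2 rose from 37.3 ± 6.13 to 89.7 ± 5.74 and 129 ± 5.15 TPM, and CYR61 fell from 542 ± 34.8 to 358 ± 26.6 and 392 ± 51.9 TPM. Of 20 Notch, Wnt and Hedgehog genes 3 rose and 2 fell with 1 uM ONO (3 and 3 adjusted over the list alone, list adjusted p = 0.39), and 4 and 2 with vilanterol (4 and 2 adjusted over the list alone, list adjusted p = 0.082, and 0.048 to 0.49 over the 5 alternatives). The Notch ligand JAG1 rose from 0.616 ± 0.0499 to 1.32 ± 0.114 and 2.12 ± 0.25 TPM.

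Of 9 prostanoid pathway genes 1, PTGES, a prostaglandin E synthase, rose with 1 uM ONO (1 adjusted over the list alone, list adjusted p = 0.73), from 2.85 ± 0.413 to 5 ± 0.629 TPM (n = 4). With vilanterol 1 rose and 1 fell (1 and 1 adjusted over the list alone, list adjusted p = 0.91, where the median was negative and the test pointed up). Of 21 interferon-stimulated genes 1 rose, ISG20, and 1 fell, IRF1, with 1 uM ONO (1 and 1 adjusted over the list alone, list adjusted p = 0.54). With vilanterol 1 rose and 1 fell (1 and 1 adjusted over the list alone, list adjusted p = 0.94, where the mean was positive and the test pointed down). The interferon list was lower with 0.1 nM ONO (list adjusted p = 0.047, median -0.17 log2) and 1 nM ONO (0.017, -0.3), with no member called. Both calls were lost with an estimated correlation (adjusted p = 0.8 and 0.75). With the other 4 alternatives the adjusted p was at most 0.065 and 0.027. Of 4 tested basal and squamous markers 1 rose and 1 fell with 1 uM ONO (1 and 1 adjusted over the list alone) and 2 rose with vilanterol (2, with 1 lower, adjusted over the list alone). Both had a list adjusted p of 0.039, 0.16 with an estimated correlation and 0.093 with the replicate block, and with vilanterol 0.051 with libraries rescaled to equal totals (at most 0.048 and 0.043 with the alternatives not named here). The keratin KRT17 rose from 307 ± 25.4 to 920 ± 108 and 1320 ± 146 TPM. Of 12 fibroblast and mesenchymal markers 1, COL3A1, rose with each agonist (1 adjusted over the list alone, list adjusted p = 0.81 and 0.35). None of 32 ribosomal protein genes was called with 1 uM ONO or vilanterol (0 adjusted over the list alone, list adjusted p = 0.47 and 0.19). As a list their median lay below vehicle in all 9 comparisons with vehicle (-0.06 to -0.02 log2), so this was not particular to RNO. The test called RNO (adjusted p = 1.2e-06), 0.1 nM ONO (0.0019), 1 nM ONO (0.0094), 0.1 nM ONO + RNO (1.8e-05) and 1 uM ONO + RNO (0.038), and with an estimated correlation none of them (0.54, 0.75, 0.78, 0.59 and 0.86). With the other 4 alternatives the adjusted p was at most 1.3e-05, 0.16, 0.019, 0.00076 and 0.056 in the same order. All 9 comparisons share the vehicle libraries, including replicate 3 with its relatively high short transcripts, and the list was not tested without that library. No member of the ciliated and secretory, endothelial or mitochondrially encoded lists was tested, and the leukocyte list had 1 tested member, CD68 (13.7 ± 1.37 TPM in vehicle), so these 4 lists had no test.

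A hypothesis was that RNO alone acts on the genes graded with ONO concentration. Over the 51 genes higher by at least 2-fold with 1 uM than with 0.1 nM ONO the mean log2 level was 3.61 ± 0.15 with RNO and 3.45 ± 0.08 in vehicle, a difference of 0.16 (exact permutation p = 0.0571, n = 4), which leaves the question open. Over the 3 genes lower in the same comparison it was 4.1 ± 0.19 with RNO and 4.68 ± 0.18 in vehicle (-0.59, exact permutation p = 0.0286, the smallest that 4 against 4 can give). RNO alone may therefore act on the genes that ONO lowers, although these are 3 genes.

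Another hypothesis was that 1 uM ONO gives the response of vilanterol at a smaller size. Of the 269 genes called between them, 97.8% (263) changed less with ONO than with vilanterol and in its direction or by under 0.1 log2, with a median ratio of 0.521. The 6 exceptions were ERRFI1, FGFR1OP2, HBEGF, NOCT, PSMD5-AS1 and ZFP36L1, named after their values were seen. Of these 2 were called with ONO and not with vilanterol: HBEGF (-0.62 log2, adjusted p = 0.011, and -0.04, adjusted p = 0.9, with vilanterol) and ZFP36L1 (-0.3, adjusted p = 0.0025, and 0.04, adjusted p = 0.72). HBEGF had the largest change with ONO of the 6 and goes against a smaller size. The share also counts genes that changed with vilanterol and by under 0.1 log2 with ONO. It therefore cannot tell a response of smaller size from one absent with ONO. Whether a smaller size accounts for most of the difference between the 2 agonists stays open. The genes were chosen for that difference, so the share describes them and no wider set.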
